A study of Ciona robusta with 15 samples.

How the data were processed

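Whole embryos of the ascidian Ciona robusta were profiled by RNA sequencing. Per the labels' protocols, fertilised eggs were electroporated with plasmids in which the enhancer of the neural gene Etr drives a coding sequence, embryos were grown at 21 °C, and 300 embryos per sample were collected at Hotta stage 19.5. Libraries were made from the purified RNA with a stranded mRNA kit. The 15 samples fall into 5 groups of 3: embryos given the fluorescent reporter Etr>Venus (control), and embryos given Etr-driven Bra, Bra with Foxa.a, Bra with Mnx, or Bra with both. The labels call the 3 samples of a group biological replicates and say no more than that they are separate, so the p-values measure only the spread between these samples, part of which may be technical.

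The authors deposited 4 tables of 15284 gene models, 1 for each group given Bra, and each table repeats the 3 control samples. The submitters' processing notes name TopHat2 2.9.8b and DESeq 1.8.1. The genome build, the read counter, its treatment of strand and its treatment of reads shared between near-identical or overlapping genes are not given in the sources used here. The deposited values are a signal that is never negative: in each column the values are whole multiples of 1 step, as gene read counts divided by a size factor would be. Dividing by that step gave whole numbers within a tolerance of 0.01 for 100% of the values in all 24 columns used, and the recovered reads of the controls were identical in the 4 tables. The step of the same control sample differed between tables, so each table had been normalised separately. A further 24 columns of log values in the same tables were not used.

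Recovered reads per library ranged from 17689915 to 26460260, and the 10 most abundant genes took 9.16% to 10.0% of them. No read fell on 305 gene models in any library. Replicates of a group differed by far more than sampling noise (chi-square per degree of freedom of at least 15.0), so no sample was counted as a copy of another.

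The test written down before the data were examined assumed raw read counts. It was the quasi-likelihood test of edgeR with TMM normalisation factors, in 1 fit of all 15 libraries. A fallback was named for normalised values, which the deposited tables hold, and the fallback was used. For the 4 comparisons with control, limma 3.58.1 in R 4.3.3 was run within each table on log2(value + 1), over genes with a mean value of at least 1, with the group as the only term, an intensity-dependent prior (limma-trend) and Benjamini-Hochberg adjustment, and genes with an adjusted p under 0.05 were called. The 6 remaining comparisons are between groups given Bra, which no deposited table holds together. For these, the recovered reads of all 15 libraries were divided by 1 set of median-of-ratios size factors, and a single limma-trend fit over the 5 groups was used. Normalised reads printed for these comparisons are therefore on a scale rebuilt across tables. Fold changes are on the log2(value + 1) scale, which understates the change of genes with few reads. They are written with their standard error, and group values as mean ± SD with n = 3.

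The files identify genes by KH gene models only, and the reference table used here holds no such identifiers. Names are given for 17 gene models whose identifier had been written beside the name before the data were examined, and the pairing of name and identifier was not checked against an annotation. These are the 3 electroporated genes, the driver gene Celf3/4/5/6 (Etr), 1 of 61 listed notochord genes, 7 of 56 neural genes, 1 of 19 muscle genes and 4 of 8 cardiac genes. The lists of endoderm (9 genes), epidermis (20), mesenchyme (10), matrix and secretory (58) and stress genes (10) had no member with a matched identifier and were not analysed here. Otx is also on the endoderm list, but its identifier had been written in the neural list only, and it was counted there. Beyond the lists, at most 2 gene models that rose and 2 that fell are named per comparison. These are the ones with the largest log2 fold change among genes with an adjusted p under 0.05, a mean of at least 1 CPM in the higher group, and all libraries of 1 group above all libraries of the other. Chance gives such a separation in 10% of unchanged genes if the libraries are interchangeable, which the pairing described next goes against. Gene lists with at least 3 members were tested with camera, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists and the 10 comparisons. Each list was also adjusted over the list alone, which for a list with 1 matched member is no adjustment.

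The replicate numbers come from the sample titles. Whether they pair the samples was checked on deviations from the group means over 14260 genes. All 30 pairs of same-numbered libraries of different groups correlated between 0.55 and 0.72, and the 60 pairs with different numbers between -0.44 and -0.12. Deviations within a group sum to 0, so the negative values follow from the positive ones and are no separate evidence. Each of the 15 libraries correlated best with its own number. The number took 46.4% of the variance and the group 32.5%. The numbers were therefore taken to pair the samples. The fit with the replicate number as a block, listed beforehand as an alternative, is given beside each result that it changes. Standard errors are those of the fit without the block, also where a call or adjusted p with the block is printed beside them. Only the interaction of KH.C7.632 carries the error of the fit with the block. In the pairwise comparisons between groups given Bra the median error over all genes was 0.106 with the block and 0.204 without.

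Further alternatives listed beforehand were no filter on low values, a stricter filter (at least 1 CPM in 3 libraries), pseudocounts of 0.1 and 5, an adjusted p under 0.01, a fit of only the libraries compared, the electroporated genes left out, DESeq2 1.42.0 on the recovered reads, an estimated inter-gene correlation, and each library left out in turn. Chosen after the data were seen were TMM factors in the limma fits, edgeR 4.0.16 (quasi-likelihood test on the recovered reads) with and without the block, all 15 libraries in the fits against control, all libraries thinned to 17689915 reads, and differences within replicate numbers that share no control. Without the block, edgeR is the test first written for raw counts, and only its use on recovered reads was the later choice. The fits were tested on simulated counts with known changes in a set of genes, drawn with the real means, library sizes and replicate-number effects. Genes with low simulated means were not among those changed, so the recoveries do not hold for genes with few reads. The means and spreads came from a fit with the block, which favours the fits with it. For the comparison of Bra with control (14059 genes), limma without the block recovered 4.48%, 46.3% and 80.3% of genes changed 1.5-, 2- and 4-fold, with 0 false calls. With the block it recovered 73.1%, 98.5% and 100%, with 4.74% of calls false. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.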

Results

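RNA of whole Ciona robusta embryos was sequenced at Hotta stage 19.5 after electroporation of fertilised eggs. The enhancer of Etr, a gene of the nervous system, placed 1 or more transcription factors in neural tissue: the T-box factor Bra, which specifies the notochord, the forkhead factor Foxa.a and the homeodomain factor Mnx. The series asks how these factors act together in notochord fate. There were 3 libraries each of control embryos (Etr>Venus), Bra, Bra+Foxa.a, Bra+Mnx and Bra+Foxa.a+Mnx embryos. Recovered reads per library averaged 21196733.7 ± 2130731.0 in control, 20890705.7 ± 1525237.8 in Bra, 23361817.3 ± 2713379.9 in Bra+Foxa.a, 20874399.7 ± 3244986.4 in Bra+Mnx and 21107610.7 ± 4113655.4 in Bra+Foxa.a+Mnx (SD, n = 3), with a full range of 17689915 to 26460260.

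The electroporated genes were read first, as a check of the labels. Reads of plasmid and endogenous transcripts cannot be told apart here, and control embryos already had reads of all 3 genes. Bra (KH.S1404.1) was at 1038 ± 326 against 635 ± 119.5 normalised reads in Bra embryos and control (log2 fold change 0.68 ± 0.23, adjusted p = 0.408, and 2.52e-08 with the replicate block). It rose by 0.90 ± 0.15 with Bra+Foxa.a (adjusted p = 0.0137), by 0.89 ± 0.15 with Bra+Mnx (adjusted p = 0.0292) and by 1.25 ± 0.14 with all 3 factors (adjusted p = 0.00200). Foxa.a (KH.C11.313) rose by 1.12 ± 0.09 where it was electroporated with Bra (adjusted p = 6.02e-04) and by 1.32 ± 0.09 with all 3 (adjusted p = 3.06e-04). It also rose in Bra+Mnx embryos, which received no Foxa.a plasmid, by 0.62 ± 0.12 (adjusted p = 0.0489), and the difference in Bra embryos, 0.37 ± 0.13, passed only with the block (adjusted p = 0.413 without and 6.89e-04 with it). Mnx (KH.L128.12) rose by 1.94 ± 0.28 with Bra+Mnx (adjusted p = 0.0135) and by 2.32 ± 0.15 with all 3 factors (adjusted p = 2.70e-04). Where Mnx was not given, its log2 fold change was -0.25 ± 0.17 with Bra and -0.79 ± 0.20 with Bra+Foxa.a, and the latter passed only with the block (adjusted p = 0.0658 without and 2.46e-04 with it).

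The members of this list were chosen by the study, so its direction is not independent evidence. The numbers of the 3 genes that rose were 0, 2, 3 and 3 in the order Bra, Bra+Foxa.a, Bra+Mnx and Bra+Foxa.a+Mnx, and 2, 2, 3 and 3 adjusted over the list alone, which also had Mnx lower in Bra+Foxa.a. As a list they were higher in 3 of the 4 groups (camera, adjusted p = 0.0438, 4.54e-07 and 8.48e-10, and 0.0960 for Bra alone). The call for Bra+Foxa.a was lost with the block (adjusted p = 0.0715) and reached adjusted p = 0.180 with an estimated correlation. The call for Bra+Foxa.a also ended without any 1 library but control replicate 2 (highest adjusted p = 0.131). Bra alone passed with the block (adjusted p = 0.0412) and without Bra replicate 3 (0.0287). In all 39 calls of a gene of the lists in the 10 comparisons the 2 groups did not overlap. This is a description only, since genes that pass such a test are chosen for separation, as the other 33 named calls were by rule. Chance parts 10% of unchanged genes if the libraries are interchangeable, which the pairing by replicate number goes against. Of single libraries, leaving out control replicate 3 or Bra+Foxa.a replicate 2 ended the call of Bra in Bra+Foxa.a (highest adjusted p = 0.0645), control replicate 2 that of Mnx in Bra+Mnx (0.0547), and any of the 6 libraries that of Foxa.a in Bra+Mnx (highest 0.192). Bra in Bra+Mnx lost its call without control replicate 1 or 3 or Bra+Mnx replicate 2 or 3 (highest 0.128).

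**Figure D1:**
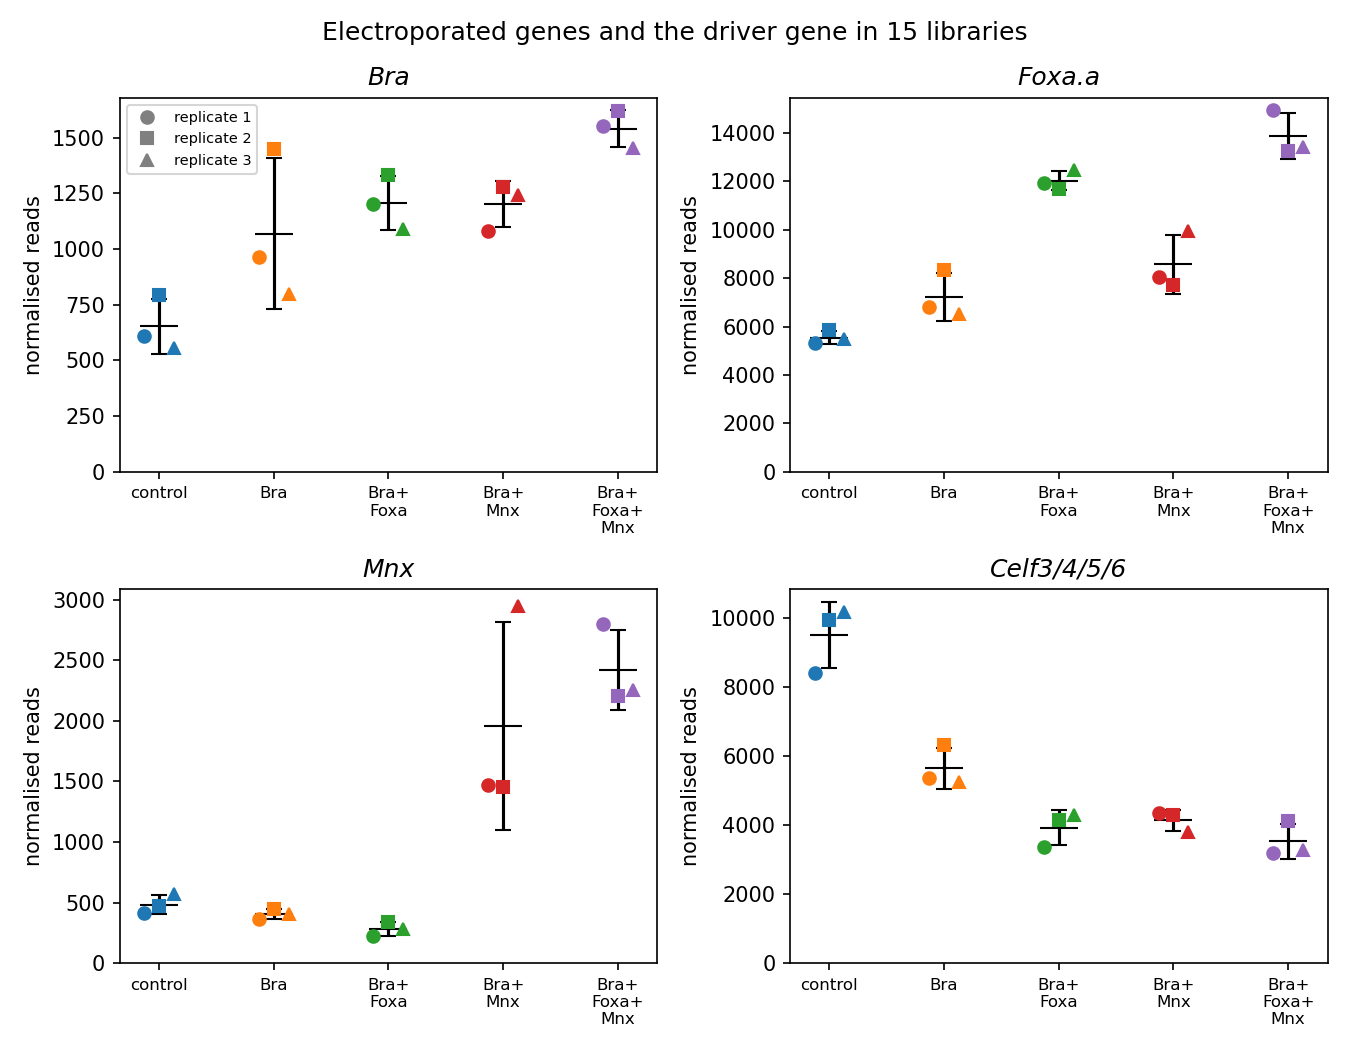
Normalised reads of Bra, Foxa.a, Mnx and Celf3/4/5/6 (vertical axes, from 0, on 1 scale rebuilt across tables) in the 5 groups (horizontal axes). Points are single libraries, shaped by replicate number, and bars are mean ± SD (n = 3). Celf3/4/5/6 was lower in each library given Bra than in any control library, and Mnx stood out in the groups given Mnx.

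Bra alone was compared with control. Bra embryos had lower transcript levels of the driver gene itself: Celf3/4/5/6 (KH.C6.128), an RNA-binding protein of the nervous system, fell (log2 fold change -0.76 ± 0.13, 5486 ± 571 against 9262 ± 938 normalised reads, adjusted p = 0.0284). Neurog (KH.C6.129), a proneural transcription factor, fell from 603 ± 31.2 to 333 ± 42.5 normalised reads (log2 fold change -0.86 ± 0.15, adjusted p = 0.0282). It was the 1 of the 7 neural genes to pass. Adjusted over the list alone 4 fell, with Otx, Ebf and Tyr added, and with the block 6 fell, all but Msx. As a list the neural genes were lower (median log2 fold change -0.53, camera adjusted p = 3.25e-08, and adjusted p = 0.0455 with an estimated correlation). Tbx2/3 (KH.L96.87), a T-box factor expressed in notochord and the 1 matched notochord gene, stood at a log2 fold change of 0.35 ± 0.16 and passed only with the block (adjusted p = 0.826 without and 8.93e-04 with it).

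In that comparison 202 genes were higher and 10 lower of 14221 tested (limma). With the replicate block the counts were 1010 and 341, and all 212 genes were called again. Of the called genes 184 rose and 2 fell at least 2-fold. The gene models KH.C4.361 and KH.C11.709 rose most, the first from 1.91 ± 0.802 to 385 ± 122 normalised reads (log2 fold change 7.05 ± 0.36, adjusted p = 1.55e-04) and the second from 23.1 ± 4.51 to 1800.0 ± 323 (log2 fold change 6.23 ± 0.21, adjusted p = 1.19e-05). KH.C9.68 (log2 fold change -1.06 ± 0.19, adjusted p = 0.0341) and KH.L144.12 (-1.01 ± 0.13, adjusted p = 0.00971) fell. The muscle gene Mrf and the 4 cardiac genes did not pass, with or without the block (cardiac list, camera adjusted p = 0.767). The count fell to 129 without control replicate 2, 116 without control replicate 3, 73 without Bra replicate 2 and 49 without Bra replicate 3. Without Bra replicate 3 the calls of Celf3/4/5/6, Neurog, KH.C9.68 and KH.L144.12 ended (adjusted p = 0.179, 0.148, 0.183 and 0.0692, the highest for each). So did those of Celf3/4/5/6 and KH.C9.68 without control replicate 2 or 3 or Bra replicate 1, that of KH.L144.12 without control replicate 2, and that of Neurog without any library but Bra replicate 1, while KH.C4.361 and KH.C11.709 passed in each of these fits.

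Bra+Foxa.a embryos were compared with control in the same way. The neural genes were lower: Ebf (KH.L24.10), a transcription factor of differentiating neurons, fell from 757 ± 102 to 277 ± 30.7 normalised reads (log2 fold change -1.45 ± 0.15, adjusted p = 0.00134). Tyr (KH.C12.469), the tyrosinase of pigment cells (-1.44 ± 0.14, adjusted p = 0.00105), and Neurog (-1.39 ± 0.14, adjusted p = 0.00111) fell. Otx (KH.C4.84), a homeodomain factor of the anterior nervous system (-0.90 ± 0.13, adjusted p = 0.00589), and the neuronal factor Pou4 (KH.C2.42, -1.15 ± 0.20, adjusted p = 0.0158) fell. In all, 5 of the 7 fell, 6 adjusted over the list alone and 6 with the block, which added Islet (KH.L152.2, log2 fold change -0.87 ± 0.20). The list was lower (median -1.15, camera adjusted p = 6.35e-10, and adjusted p = 0.0455 with an estimated correlation).

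The driver gene Celf3/4/5/6 fell (-1.28 ± 0.13, adjusted p = 0.00118) and Tbx2/3 rose by 0.58 ± 0.11 (adjusted p = 0.0222) in Bra+Foxa.a embryos. Across 14254 genes 528 were higher and 190 lower (limma), and with the block 1768 and 1704, with all 718 called again. KH.C4.361 (log2 fold change 6.92 ± 0.35) and KH.C11.709 (6.61 ± 0.21) again rose most. KH.C3.755 (log2 fold change -2.41 ± 0.50, adjusted p = 0.0313) and KH.C12.152 (-2.41 ± 0.38, adjusted p = 0.00903) fell. The muscle regulator Mrf (KH.C14.307) stood at -0.45 ± 0.11 and passed only with the block (adjusted p = 0.0519 without and 3.01e-04 with it). No cardiac gene passed (camera adjusted p = 0.512), and with the block Hand-r (KH.C1.1116, log2 fold change 0.43 ± 0.18) was higher and Foxf (KH.C3.170, -0.26 ± 0.15) lower. The number called fell to 463 without control replicate 3, 462 without Bra+Foxa.a replicate 2 and 408 without Bra+Foxa.a replicate 3. Tbx2/3 lost its call without control replicate 1 or 3 or Bra+Foxa.a replicate 2 or 3 (highest adjusted p = 0.0980), Pou4 without control replicate 2 or Bra+Foxa.a replicate 3 (0.0523), and KH.C3.755 without any library but Bra+Foxa.a replicate 1 (0.105).

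In Bra+Mnx embryos, these neural genes fell against control: Neurog (log2 fold change -1.06 ± 0.13, adjusted p = 0.00924), Ebf (-1.15 ± 0.14, adjusted p = 0.00743), Tyr (-1.31 ± 0.19, adjusted p = 0.0138) and Otx (-0.85 ± 0.12, adjusted p = 0.0123). Thus 4 of the 7 fell, 6 adjusted over the list alone and 6 with the block, which added Pou4 (log2 fold change -0.87 ± 0.24) and Islet (-0.61 ± 0.23). The list was lower (median -0.87, camera adjusted p = 4.29e-11, and adjusted p = 0.0372 with an estimated correlation). The driver, Celf3/4/5/6, fell from 9418 ± 955 to 4093 ± 292 normalised reads (adjusted p = 0.00342). Tbx2/3 stood at 0.40 ± 0.11 and passed only with the block (adjusted p = 0.175 without and 0.00238 with it). Its p-value over the list alone was under the threshold, but as the 1 matched member of its list it is unadjusted there.

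Of 14222 genes tested in Bra+Mnx embryos 209 were higher and 56 lower (limma), and 922 and 934 with the block, with all 265 called again, while edgeR called 498 without the block. KH.C11.709 rose by 6.49 ± 0.25 (adjusted p = 7.54e-05) and KH.C1.36, with a control mean of 0.290 ± 0.502 normalised reads, reached 110.0 ± 57.9 (adjusted p = 0.00323). KH.L119.26 (-1.70 ± 0.30, adjusted p = 0.0307) and KH.C14.119 (-1.66 ± 0.29, adjusted p = 0.0322) fell. No cardiac gene passed, 1 fell adjusted over the list alone, Nkx2-5 (KH.C8.482, log2 fold change -0.48 ± 0.11), and with the block Nkx2-5 and Foxf (-0.27 ± 0.13) were lower (list, camera adjusted p = 0.0649). Mrf stood at -0.46 ± 0.15 and passed with the block (adjusted p = 0.0441). The count fell to 132 and 102 without control replicates 2 and 3, and to 78 and 133 without Bra+Mnx replicates 2 and 3. Otx lost its call without control replicate 2 or 3 or Bra+Mnx replicate 2 (highest adjusted p = 0.0598), Neurog and Tyr without control replicate 3 or Bra+Mnx replicate 2 (0.0526 and 0.0640), KH.L119.26 without any library but control replicate 1 (0.146) and KH.C14.119 without any 1 of the 6 (0.155).

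With all 3 factors the neural list had its lowest median against control, while its difference from Bra+Foxa.a did not pass (camera adjusted p = 0.178). Total Bra also had its largest rise against control in this group, so the neural falls are not separated from its level. Tyr fell from 1027 ± 167 to 336 ± 65.2 normalised reads (log2 fold change -1.61 ± 0.18, adjusted p = 0.00179). Also lower were Neurog (-1.48 ± 0.12, adjusted p = 4.73e-04), Ebf (-1.46 ± 0.19, adjusted p = 0.00397), Pou4 (-1.23 ± 0.20, adjusted p = 0.0118) and Otx (-1.06 ± 0.11, adjusted p = 0.00162). Thus 5 of 7 fell, 5 adjusted over the list alone, and all 7 with the block, Msx (KH.C2.957) at -0.35 ± 0.26 and Islet at -0.57 ± 0.29 included. The list was lower (median -1.23, camera adjusted p = 4.29e-11, and adjusted p = 0.0451 with an estimated correlation). Celf3/4/5/6 fell (-1.44 ± 0.13, adjusted p = 6.38e-04), and Tbx2/3 rose from 2388 ± 245 to 3697 ± 135 normalised reads (adjusted p = 0.0106).

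Bra+Foxa.a+Mnx embryos had 401 genes higher and 165 lower than control of 14213 tested (limma), and 1117 and 949 with the block, with all 566 called again. KH.C11.709 (log2 fold change 6.50 ± 0.23, adjusted p = 1.56e-05) and KH.C8.898 (5.93 ± 0.39, adjusted p = 2.70e-04) rose most. KH.L116.39 (-2.47 ± 0.54, adjusted p = 0.0411) and KH.C14.100 (-2.18 ± 0.41, adjusted p = 0.0212) fell. Mrf stood at -0.43 ± 0.12 and passed with the block (adjusted p = 0.0126), as did Hand-r at 0.38 ± 0.21 (adjusted p = 0.0105). No cardiac gene passed without the block (list, camera adjusted p = 0.767). The camera direction of this list, and in Bra against control, was down although its median and mean were above 0. Calls dropped to 377 and 358 without control replicates 2 and 3, and to 363 and 280 without Bra+Foxa.a+Mnx replicates 1 and 3. Tbx2/3 lost its call without Bra+Foxa.a+Mnx replicate 3 (adjusted p = 0.0541), KH.L116.39 without any library but Bra+Foxa.a+Mnx replicate 1 (highest 0.129) and KH.C14.100 without control replicate 1 or 3 or Bra+Foxa.a+Mnx replicate 1 (0.0987).

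**Figure D2:**
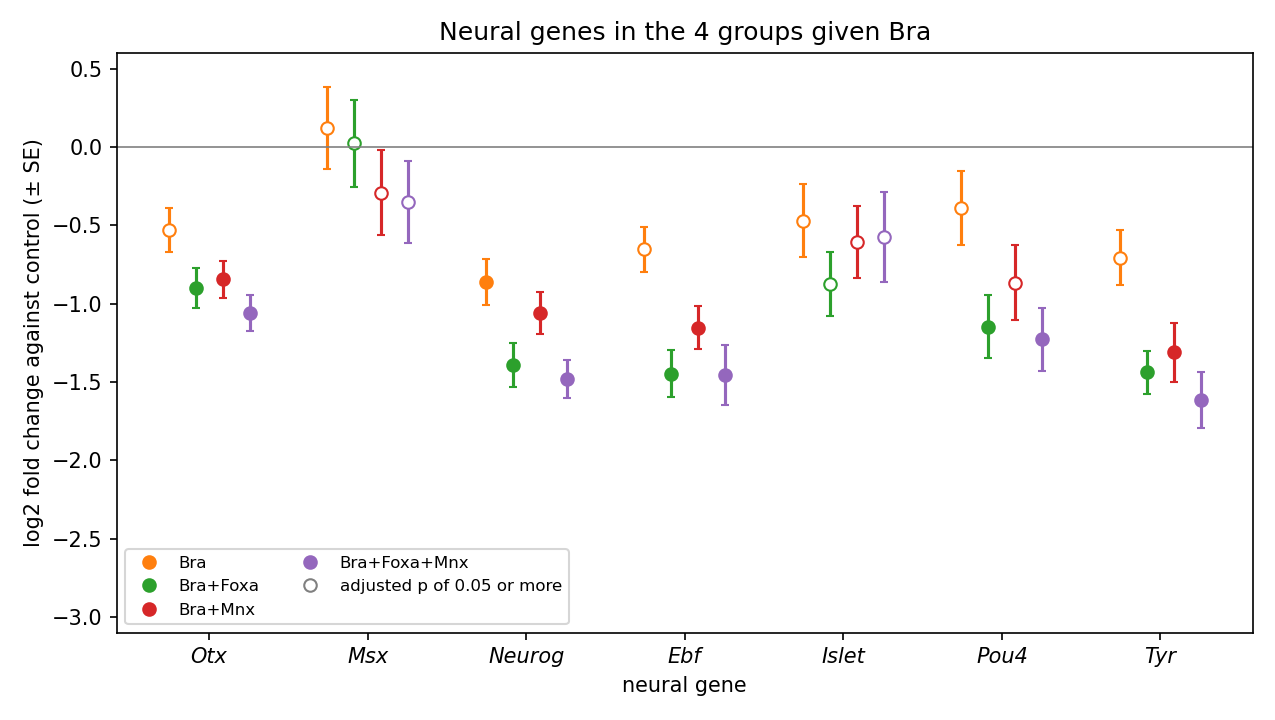
Log2 fold change against control (vertical axis, ± SE, n = 3 against 3) of the 7 neural genes (horizontal axis) in the 4 groups given Bra, coloured by group. Filled points passed limma at an adjusted p under 0.05. Otx, Neurog, Ebf, Islet, Pou4 and Tyr lay below 0 in all 4 groups, and Msx and Islet had no filled point.

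The 4 comparisons with control were set side by side. Of the 202 genes higher with Bra alone, 182 were also called higher with Bra+Foxa.a, 130 with Bra+Mnx and 138 with all 3 factors. The 10 genes lower with Bra alone were called lower in each of the other groups. Over all 4 comparisons 650 genes were higher in at least 1 and 113 in all, and 235 were lower in at least 1 and 10 in all. No gene was higher in one and lower in another (limma without the block), and 30 were with it. The log2 fold changes of pairs of comparisons correlated across genes at r = 0.72 to 0.84, against 0.50 in 100 simulations of unchanged groups with the same controls. Their covariance was 0.200 to 0.286, against 0.0324 to 0.0327 simulated. Differences within 1 replicate number for one group and within another number for the other share no control, and over the 6 such pairings their mean covariance was 0.165 to 0.249 (mean r = 0.40 to 0.52). Independent lists would share 7.54 higher genes between Bra and Bra+Foxa.a and 14.9 between Bra+Foxa.a and Bra+Foxa.a+Mnx, where 182 and 308 were shared, and 2.21 lower genes in the latter pair, where 121 were shared. Simulated unchanged groups made 0 calls, so the 0 that they shared is no measure for these overlaps. The 3 control libraries cannot be parted into 2 sets of at least 2, so part of the excess of shared calls may come from the shared controls.

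Bra+Foxa.a was compared with Bra to see what adding Foxa.a changed. Foxa.a itself rose by 0.74 ± 0.11 (12021 ± 400.4 against 7219 ± 974 normalised reads, adjusted p = 0.0111). The neural genes were lower as a list (median log2 fold change -0.53, camera adjusted p = 1.77e-10, and adjusted p = 0.0230 with an estimated correlation). None of the 7 passed on its own, while 5 fell adjusted over the list alone and 5 with the block, Ebf at -0.80 ± 0.16, Pou4 at -0.76 ± 0.22, Tyr at -0.73 ± 0.19, Neurog at -0.53 ± 0.13 and Otx at -0.37 ± 0.12. The driver gene Celf3/4/5/6 stood at -0.52 ± 0.13 and passed with the block (adjusted p = 0.00142), as did Mrf (-0.38 ± 0.14, adjusted p = 0.0370) and Hand-r (0.34 ± 0.20, adjusted p = 0.0147).

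Of 14260 genes 31 were higher and 11 lower with Bra+Foxa.a than with Bra (limma), and 326 and 347 with the block. KH.C9.887 rose from 9.44 ± 2.08 to 160.0 ± 100.2 normalised reads (adjusted p = 0.00763) and KH.C4.259 from 9.41 ± 4.63 to 98.4 ± 31.3 (adjusted p = 0.00253). KH.L147.40 fell from 222 ± 57.6 to 36.1 ± 14.6 (adjusted p = 0.00560) and KH.C1.812 from 52.4 ± 29.6 to 11.7 ± 3.55 (adjusted p = 0.0416). The electroporated list was higher (camera adjusted p = 0.0473), but not with the block (adjusted p = 0.106) and at adjusted p = 0.216 with an estimated correlation, and the cardiac list did not pass (adjusted p = 0.229). The electroporated call also ended without any library but Bra replicate 2 (highest adjusted p = 0.250). The count fell to 13 and 22 without Bra replicates 1 and 3, and to 20, 22 and 5 without Bra+Foxa.a replicates 1, 2 and 3. KH.C9.887 and KH.L147.40 lost the call only without Bra+Foxa.a replicate 3 (adjusted p = 0.0526 and 0.0515), Foxa.a without that library or Bra replicate 1 or 3 (0.0741), and KH.C1.812 without any 1 of the 6 (0.240). With only the compared libraries in the fit 10 genes were called, and Foxa.a (0.165) and KH.C1.812 (0.315) were not.

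Bra+Mnx was compared with Bra to see what adding Mnx changed. Mnx rose by 2.19 ± 0.24 (1957 ± 860.0 against 406 ± 41.1 normalised reads, adjusted p = 0.00485). The only other gene higher was KH.S964.1 (log2 fold change 2.38 ± 0.35, adjusted p = 0.0316), and KH.C3.446 (-2.82 ± 0.36, adjusted p = 0.0136) and KH.C7.395 (-2.29 ± 0.31, adjusted p = 0.0192) were lower, of 14260 tested (limma). With the block 70 were higher and 119 lower, and the total of 4 became 36 with DESeq2 and 220 with edgeR and the block. The neural list was lower (median -0.41, camera adjusted p = 1.67e-07, and adjusted p = 0.0442 with an estimated correlation) with no member past the threshold, 2 adjusted over the list alone and 2 with the block, Msx (-0.41 ± 0.31) and Ebf (-0.50 ± 0.16). The cardiac list was lower as well (median -0.26, camera adjusted p = 0.0188), at adjusted p = 0.0536 with an estimated correlation, with Nkx2-5 at -0.40 ± 0.13 passing adjusted over the list alone and with the block (adjusted p = 0.0388). The cardiac gene with the largest fall, Mesp (KH.C3.100, -0.45), had only 5 to 7 recovered reads in the Bra+Mnx libraries. The driver gene Celf3/4/5/6 stood at -0.44 ± 0.13 and passed with the block (adjusted p = 0.0167). The electroporated list was higher (adjusted p = 9.28e-08). The count of 4 fell to 2 without Bra replicate 2 and to 1 without Bra replicate 3 or any of the 3 Bra+Mnx libraries. The cardiac call ended without Bra replicate 2 or Bra+Mnx replicate 3 (adjusted p = 0.0800 and 0.0869), and those of KH.S964.1, KH.C3.446 and KH.C7.395 without Bra replicate 3 (0.249, 0.111 and 0.210, the highest for each) or any Bra+Mnx library. KH.S964.1 also lost its call without Bra replicate 1 or 2 and KH.C7.395 without Bra replicate 2. With only the compared libraries in the fit 2 genes, both lower, were called, and Mnx (0.102), KH.S964.1 (0.127) and KH.C7.395 (0.138) were not.

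Against Bra alone, embryos given all 3 factors had lower Tyr (-0.91 ± 0.19, adjusted p = 0.0421), Ebf (-0.80 ± 0.16, adjusted p = 0.0350), Neurog (-0.62 ± 0.13, adjusted p = 0.0481) and Celf3/4/5/6 (-0.68 ± 0.13, adjusted p = 0.0277). Of the 7 neural genes 3 fell, 5 adjusted over the list alone and 6 with the block, all but Islet (list median -0.62, camera adjusted p = 9.41e-11, and adjusted p = 0.0230 with an estimated correlation). Foxa.a rose by 0.95 ± 0.11 and Mnx by 2.57 ± 0.24, and Bra stood at 0.57 ± 0.18, passing adjusted over the list alone and with the block (adjusted p = 0.289 without and 0.00265 with it). The neural falls here are therefore not separated from a higher total level of Bra. With the block Tbx2/3 (0.28 ± 0.13) and Hand-r (0.29 ± 0.20) were called higher and Mrf (-0.37 ± 0.14) lower. The errors printed here are those of the fit without the block.

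In total 55 genes were higher and 65 lower with the 3 factors than with Bra (limma), and 364 and 564 with the block. The larger share turned to higher genes with only the compared libraries in the fit (23 calls, 69.6% higher) and at an adjusted p under 0.01 (18 calls, 66.7% higher). It also turned without Bra replicate 2 (75% higher) or 3 (60%) or Bra+Foxa.a+Mnx replicate 1 (60.7%) or 3 (53.6%). KH.C1.707 rose from 1.48 ± 1.28 to 43.5 ± 4.37 normalised reads (adjusted p = 0.0183) and KH.C11.373 from 15.1 ± 6.50 to 188 ± 49.6 (adjusted p = 0.00266). KH.C7.395 fell from 401 ± 134 to 32.6 ± 6.08 (adjusted p = 3.14e-04) and KH.C9.860 from 38.8 ± 22.4 to 1.98 ± 2.17 (adjusted p = 0.0306). The electroporated list was higher (camera adjusted p = 7.16e-12) and the cardiac list did not pass (adjusted p = 0.931, direction up, with a median of -0.02 and a mean of 0.02). The number called fell to 55, 48 and 35 without Bra replicates 1, 2 and 3, and to 28, 73 and 28 without replicates 1, 2 and 3 of the group given all 3 factors. Tyr, Ebf and Celf3/4/5/6 lost the call without any library but Bra+Foxa.a+Mnx replicate 2, and Neurog without any 1 of the 6, with the highest adjusted p (0.203, 0.163, 0.135 and 0.186) without Bra+Foxa.a+Mnx replicate 1. KH.C1.707 lost it without Bra replicate 1 or Bra+Foxa.a+Mnx replicate 1 or 3 (highest 0.0908), and KH.C9.860 without Bra replicate 1 or 3 or Bra+Foxa.a+Mnx replicate 1 or 2 (0.136). With only the compared libraries the calls of Tyr (0.157), Ebf (0.211), Neurog (0.302), Celf3/4/5/6 (0.129) and KH.C9.860 (0.108) ended.

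Where Mnx was added to Bra+Foxa.a, far more genes were lower than higher. Mnx rose by 3.11 ± 0.24 (2418 ± 330.2 against 282 ± 59.7 normalised reads, adjusted p = 6.20e-05), 1 of 2 genes higher, and 31 genes were lower of 14260 (limma). With the block 55 were higher and 255 lower. KH.S1233.2 fell from 77.1 ± 18.3 to 6.20 ± 3.03 (adjusted p = 0.0465) and KH.L153.43 from 28.6 ± 5.27 to 2.93 ± 1.57 (adjusted p = 0.0227). The neural list did not pass (median -0.09, camera adjusted p = 0.178). Of its genes Msx alone was lower with the block (log2 fold change -0.37, adjusted p = 0.0264, with a standard error of 0.31 without the block). Bra stood at 0.35 ± 0.18, Foxa.a at 0.20 ± 0.11 and Celf3/4/5/6 at -0.16 ± 0.13, none past the threshold. In the fit with the block Bra had 95% limits of 0.123 to 0.585, not adjusted over genes, and was higher in all 3 replicate numbers. The electroporated list was higher (adjusted p = 3.46e-10) and the cardiac list did not pass (adjusted p = 0.217). Calls dropped to 8, 17 and 7 without Bra+Foxa.a replicates 1, 2 and 3, and to 11, 10 and 12 without Bra+Foxa.a+Mnx replicates 1, 2 and 3. The neural list passed without Bra+Foxa.a replicate 1 (adjusted p = 0.0322) or Bra+Foxa.a+Mnx replicate 2 (0.00879), KH.S1233.2 lost its call without any 1 of the 6 libraries (highest 0.271) and KH.L153.43 without any but Bra+Foxa.a+Mnx replicate 3 (0.143). With only the compared libraries 17 genes were called, and KH.L153.43 was not (0.0752).

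Adding Foxa.a to Bra+Mnx raised Foxa.a by 0.70 ± 0.11 (13868 ± 939.8 against 8562 ± 1216 normalised reads, adjusted p = 0.0285). KH.C9.887 rose by 3.28 ± 0.52 (adjusted p = 0.0285) and KH.L147.40 fell (-2.48 ± 0.35, adjusted p = 0.0134), the directions they had when Foxa.a was added to Bra alone. KH.C5.659 rose by 3.22 ± 0.48 (adjusted p = 0.0214) and KH.C6.217 fell (-1.68 ± 0.27, adjusted p = 0.0285). The neural list was lower (median -0.30, camera adjusted p = 1.07e-04), at adjusted p = 0.0960 with an estimated correlation, with no member past the threshold and 1 adjusted over the list alone. The cardiac list was higher (median 0.26, camera adjusted p = 0.00704, and adjusted p = 0.0442 with an estimated correlation), with no member called. This call shares the Bra+Mnx libraries with the lower cardiac call in Bra+Mnx against Bra, so they are not independent results. Mesp, with few reads, again had the largest change of the cardiac genes (0.42). Together 15 genes were higher and 3 lower (limma), and 151 and 109 with the block, and the electroporated list was higher (adjusted p = 4.54e-07). The number called fell to 5, 0 and 10 without Bra+Mnx replicates 1, 2 and 3, and to 1, 3 and 0 without Bra+Foxa.a+Mnx replicates 1, 2 and 3, with 40% of the 5 and 0% of the 1 higher. Foxa.a and KH.C9.887 lost the call without any library but Bra+Mnx replicate 3 (highest adjusted p = 0.180 and 0.175), KH.C6.217 without any but Bra+Mnx replicate 1 (0.180), KH.C5.659 without any 1 of the 6 (0.155), and KH.L147.40 without Bra+Mnx replicate 2 or 3 or Bra+Foxa.a+Mnx replicate 1 or 3 (0.119). The neural list lost its call without Bra+Foxa.a+Mnx replicate 1 (adjusted p = 0.0718) and the cardiac list without Bra+Mnx replicate 3 (0.0589). With only the compared libraries no gene was called, with Foxa.a at adjusted p = 0.244, KH.C9.887 at 0.226, KH.C5.659 and KH.L147.40 at 0.0771 and KH.C6.217 at 0.263.

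**Figure D3:**
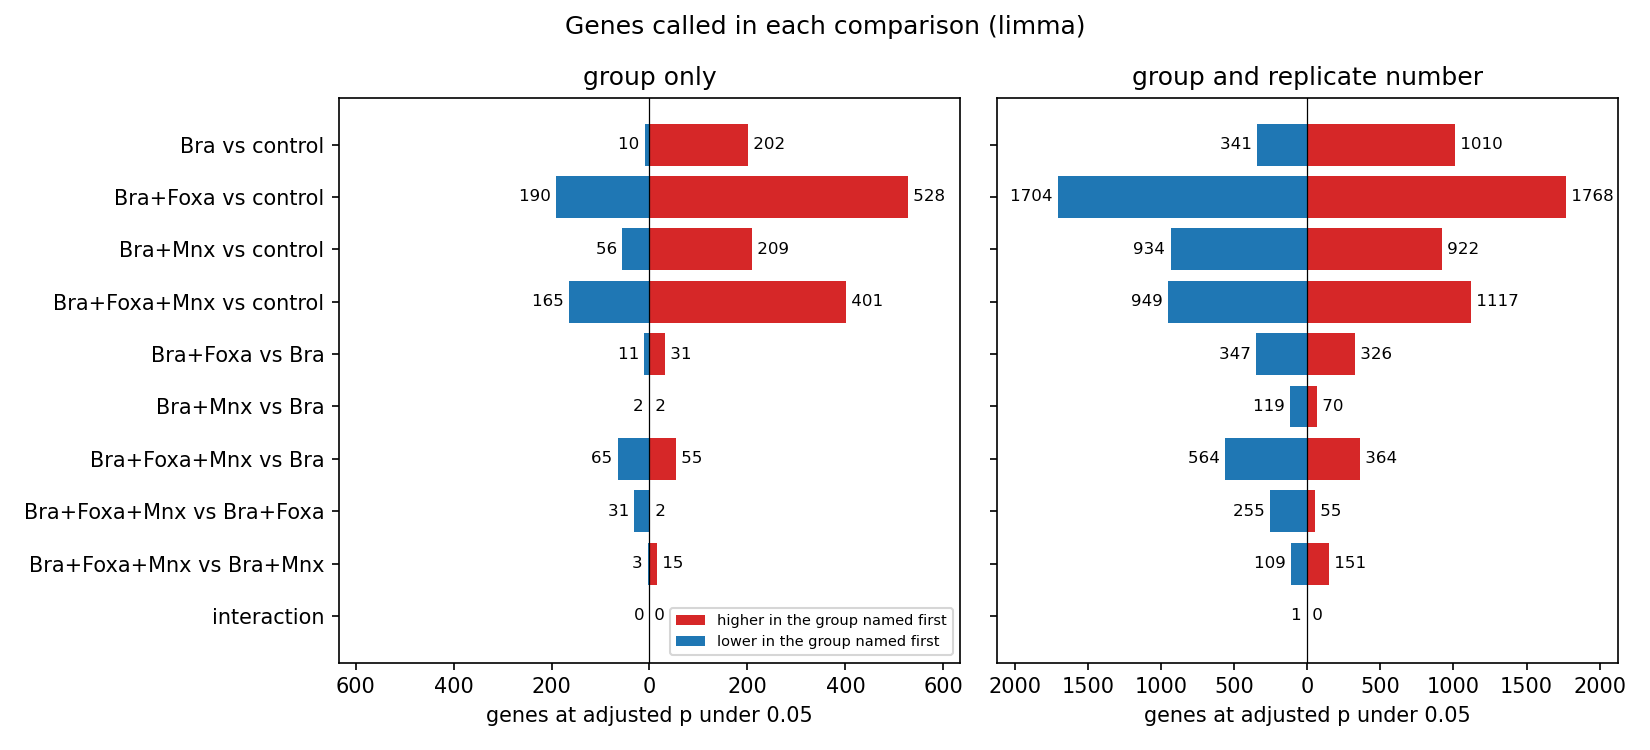
Genes with an adjusted p under 0.05 (horizontal axes, limma) in the 10 comparisons (vertical axis), higher to the right in red and lower to the left in blue. The left panel fits the group only and the right panel adds the replicate number as a block, on a wider axis. With the block the counts for Bra against control went from 202 and 10 to 1010 and 341.

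The interaction of Foxa.a and Mnx was tested on the Bra background, to see whether the change on adding both differed from the sum of the 2 single changes. For the 7 neural genes the median interaction term was 0.39 on the log2 scale, so that they were lower with both factors by less than that sum (camera adjusted p = 2.81e-04, and adjusted p = 0.114 with an estimated correlation). None of the 7 passed on its own, adjusted over the list alone or with the block. The electroporated list had a positive term (median 0.14, adjusted p = 0.0438), lost with the block (adjusted p = 0.0818) and at adjusted p = 0.214 with an estimated correlation, and the cardiac list did not pass (adjusted p = 0.251). No gene of 14260 passed (limma, smallest adjusted p = 0.157), with 162 at an unadjusted p under 0.05. With the block KH.C7.632 passed, a gene named because it was the 1 call and so chosen after its values were seen. It stood at 95.2 ± 20.6 normalised reads with Bra, 309 ± 29.9 with Bra+Foxa.a, 117 ± 18.7 with Bra+Mnx and 116 ± 4.85 with all 3 factors (interaction -1.70 ± 0.20, adjusted p = 0.00171). The quasi-likelihood test of edgeR called 0 genes, and 6 with the block, and DESeq2 called 1. Leaving out Bra+Foxa.a replicate 1 ended the neural call (adjusted p = 0.0594), and leaving out Bra replicate 2, Bra+Foxa.a replicate 1 or 3, Bra+Mnx replicate 1 or 2, or Bra+Foxa.a+Mnx replicate 1 ended that of the electroporated list (highest 0.630).

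**Figure D4:**
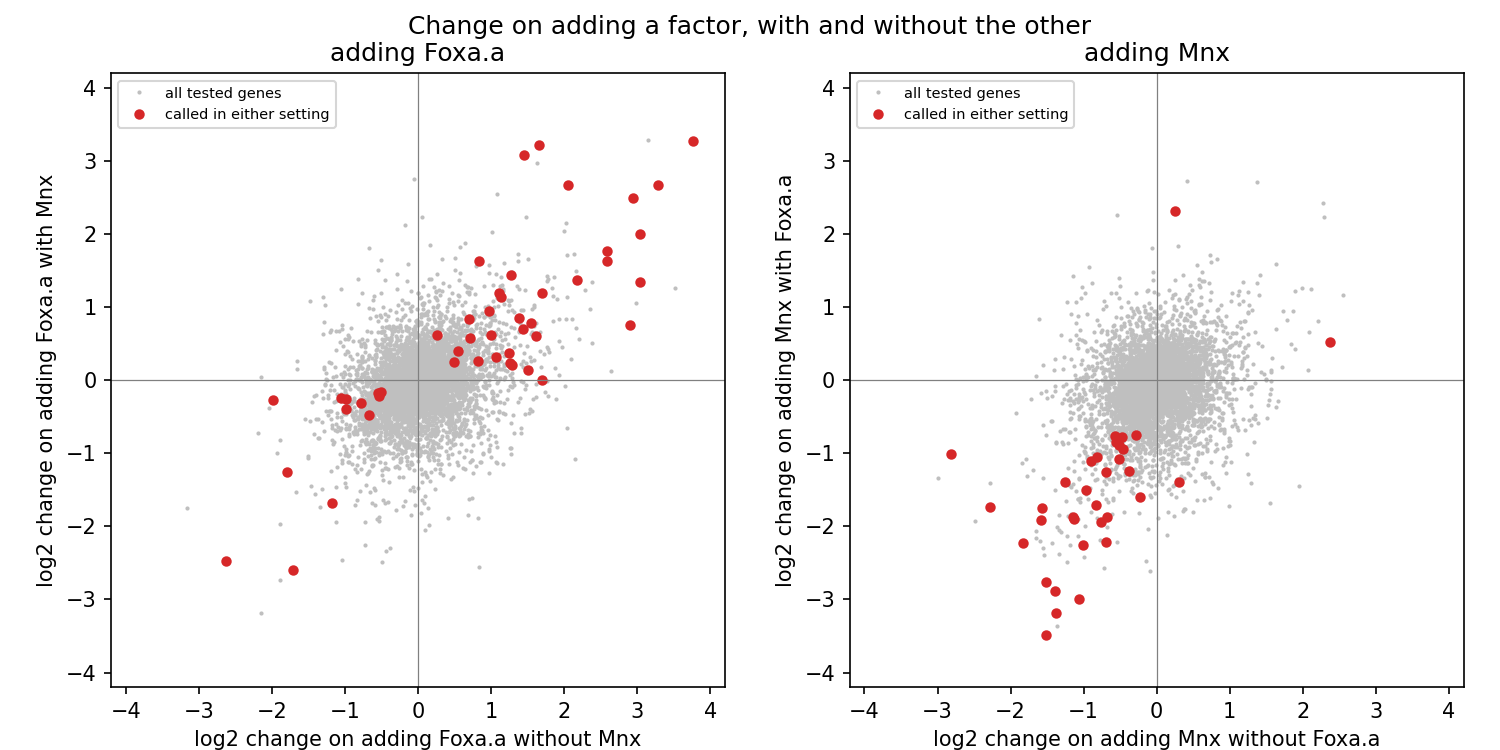
Log2 change of each tested gene on adding Foxa.a (left) or Mnx (right), without the other factor (horizontal axes) and with it (vertical axes). The 4 sets of libraries behind the 2 axes of a panel are not shared, the 3 electroporated genes are left out, and genes called in either setting are red. All 41 genes called on adding Foxa.a to Bra, and 31 of 32 called on adding Mnx to Bra+Foxa.a, had the same sign on both axes.

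The change on adding a factor was compared between the 2 settings, which share no library. Over 14257 genes, the change on adding Foxa.a without Mnx correlated with that in its presence at r = 0.36 across genes, and the change on adding Mnx without and with Foxa.a at r = 0.28, where genes are not independent replicates. The 41 genes called on adding Foxa.a to Bra all had the same sign when it was added to Bra+Mnx, with a median size of 1.29 on the log2 scale in the first setting and 0.61 in the second. Of the 32 genes called on adding Mnx to Bra+Foxa.a, 31 had the same sign when it was added to Bra, with medians of 1.72 and 0.82. Sizes in the setting that made the call are raised by that choice, so the medians do not test a difference in size. With the block, 622 of 672 genes called on adding Foxa.a to Bra kept their sign in the other setting, as did 278 of 309 called on adding Mnx to Bra+Foxa.a. In that fit 149 genes were called in the same direction for Foxa.a in both settings and 81 for Mnx. Independent lists would share 6.07 and 2.39. Both settings were tested in 1 fit with 1 estimate of the spread per gene, which favours the same genes in both lists. The excess over independent lists is therefore no measure of shared effects alone.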

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

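The tests of plasmid dose, of the spread between replicate numbers and of the levels of Bra and Foxa.a given here were chosen after the results were seen, as were TMM factors and thinning as settings and the regroupings within replicate numbers.

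The interaction of Foxa.a and Mnx on the Bra background passed a threshold for 3 results, each in some of the fits only. The median interaction term was 0.14 on the log2 scale for the electroporated list, whose camera call was lost with the replicate block (adjusted p = 0.0818) and with an estimated correlation (0.214). It was 0.39 for the neural list, lost with an estimated correlation (0.114). The term of KH.C7.632 was -1.70 with the block (adjusted p = 0.00171), while without it the smallest adjusted p of any gene was 0.157.

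Samples with the same replicate number deviated together from their group means. Library depth alone does not account for this: after thinning all libraries to equal reads the median correlation of same-numbered libraries of different groups was 0.589. A dose of the electroporated factors that differs between numbers is argued against by the control libraries, which received none of the 3 factors and whose lowest correlation with a same-numbered treated library was 0.545. Other differences between numbers, such as the parents of the eggs, the day or the library batch, were not tested, as the labels give none of them.

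Most genes called with Bra alone were higher than in control. Normalization stays open: 94.8% of calls were higher with TMM factors, but these moved the median of all genes by only -0.00842 (log2), too little to test it. The spread between replicate numbers may hide smaller falls: with the block the share of higher calls dropped by 20.5 percentage points, from 95.3% to 74.8%. Higher calls still outnumbered lower ones in that fit, 1010 to 341, and a biological explanation was not tested.

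Most genes that differed between Bra+Foxa.a+Mnx and Bra+Foxa.a were lower with all 3 factors. Depth as the whole cause is argued against, as 93.5% of calls were lower after thinning to equal reads. Normalization stays open, since TMM factors, with 93.5% of calls lower, moved the median of all genes by only -0.00753 (log2). A lower total level of Bra when 3 plasmids are given together is argued against. The 95% limits of the Bra difference were 0.123 to 0.585 (log2, fit with the block, not adjusted over genes). The groups may thus differ in total Bra as well as in Mnx, and this comparison does not separate the 2. A fall in total Foxa.a beyond -0.1 is argued against as well, by limits of -0.00226 to 0.411. That bound was set after the limits were seen, and a bound at no change would leave a lower level of Foxa.a undecided. Plasmid and endogenous transcripts were counted together in whole embryos, so a lower plasmid dose masked by endogenous reads stays open. An effect of Mnx itself, the biological explanation that the design names, stays open too.

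The groups of 3 against 3 allow 10 splits of their 6 libraries, too few for a share under 0.05. For the 4 comparisons with control the real splits gave 212, 718, 265 and 566 calls, and for the 5 between groups given Bra 42, 4, 120, 33 and 18. Each was the 1 split with as many calls, and the highest other split gave 0 in all 9, also among the 4 splits, the real one included, that part all 3 pairs. The others mix the groups within replicate numbers in part. Every split but the real one mixes the 2 groups, so a real difference adds to the spread and lowers the calls. The 0 calls of the other splits are therefore no separate support. For the interaction, with 0 real calls, all 100 of 100 regroupings give as many by construction, so this count is no test of chance. The highest other regrouping gave 2082 calls, which points to a structure of the samples. It set 4 libraries numbered 3 and 2 numbered 2 against the rest, but others as uneven gave 0. The next, with 58, set both groups given Mnx against the rest, which is the effect of Mnx. With the block, 12 of 100 regroupings within replicate numbers, the real one included, gave at least the 1 real call, and the highest other gave 507. Regroupings hold the effects of Foxa.a and Mnx themselves, so neither count measures chance for an interaction, and chance was not tested for that call.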

How the results depend on the processing

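Tests chosen after the data were seen were edgeR on the recovered reads with and without the block, TMM factors in the limma fits, thinned libraries and all 15 libraries in the fits against control. Without the block, edgeR is the test first written for raw counts. The values follow the order Bra, Bra+Foxa.a, Bra+Mnx and Bra+Foxa.a+Mnx against control, then Bra+Foxa.a, Bra+Mnx and Bra+Foxa.a+Mnx against Bra, Bra+Foxa.a+Mnx against Bra+Foxa.a and against Bra+Mnx, and the interaction. Counts of changed genes were 1351, 3472, 1856, 2066, 673, 189, 928, 310, 260 and 1 with the block. They were 1071, 2772, 1857, 2312, 738, 220, 954, 369, 299 and 6 with edgeR and the block, and 470, 1157, 718, 933, 158, 36, 276, 90, 44 and 1 with DESeq2. At an adjusted p under 0.01 they were 70, 351, 80, 260, 12, 1, 18, 8, 0 and 0. With only the compared libraries in the fit the 5 comparisons between groups given Bra gave 10, 2, 23, 17 and 0. All 15 libraries gave 339 for Bra and 493 for Bra+Mnx against control. Without the block edgeR gave 316, 877, 498, 660, 44, 4, 113, 33, 15 and 0. Counts with TMM factors, other filters, other pseudocounts, thinned libraries or the electroporated genes left out stayed within 1.5-fold.

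Of the list tests, the electroporated genes in Bra passed with all 15 libraries (adjusted p = 0.0274) and with the block (0.0412). In Bra+Foxa.a against control they lost the call with the block (0.0715) and with an estimated correlation (0.180). Against Bra the same list lost it with the block (0.106), the compared libraries only (0.172) and an estimated correlation (0.216), and in the interaction with the block (0.0818) and an estimated correlation (0.214). With an estimated correlation alone the calls of the cardiac list in Bra+Mnx against Bra (0.0536), and of the neural list in Bra+Foxa.a+Mnx against Bra+Mnx (0.0960) and in the interaction (0.114), were lost. The block changed no other list call.

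With 1 library left out, counts ranged in the same order from 49 to 283, 408 to 583, 78 to 341, 280 to 501, 5 to 29, 1 to 5, 28 to 73, 7 to 17, 0 to 10 and 0 to 0. Adjusted p of the electroporated list ranged from 0.0287 to 0.312 for Bra and 0.0266 to 0.131 for Bra+Foxa.a against control, 0.00196 to 0.250 for Bra+Foxa.a against Bra and 0.000323 to 0.630 for the interaction. Those of the neural list ranged from 0.00879 to 0.754 against Bra+Foxa.a, 8.93e-07 to 0.0718 against Bra+Mnx and 5.09e-06 to 0.0594 for the interaction. The cardiac list ranged from 0.0188 to 0.0869 for Bra+Mnx against Bra and 0.00421 to 0.0589 for Bra+Foxa.a+Mnx against Bra+Mnx. Its direction turned, with no call, in Bra+Foxa.a+Mnx against control (0.603 to 0.944) and against Bra (0.577 to 0.989), as did that of the neural list against Bra+Foxa.a. The uncalled interaction terms of Bra (-0.0998 to 0.333) and Foxa.a (-0.152 to 0.0722) also changed sign. Of 72 calls of named genes 33 held without each library in turn and 0 changed sign. Over the 14 other alternatives 1472 of 1659 values of named genes kept their side of the threshold, 78 lost and 109 gained a call, and 0 were reversed. Of those lost, 36 were at an adjusted p under 0.01 and 16 with only the compared libraries. The cause was not tested for any of these, except that fits of fewer libraries have fewer degrees of freedom.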

Other observations

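The medians by replicate number and over the splits, and the counts with edgeR on the recovered reads, were chosen after the results were seen.

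Genes raised by Bra with Mnx may rise further when Foxa.a is added to Bra. Over the 206 genes raised in Bra+Mnx embryos, the 3 electroporated genes left out, the median log2 fold change of Bra+Foxa.a against Bra was 0.19, above all of 10000 random lists matched on expression (95% of them between -0.03 and 0.02), and 140 of the genes were higher. Random lists do not measure the spread between libraries or in dose, where Bra itself stood at 0.22 ± 0.18. The median was 0.45, 0.10 and 0.06 for replicate numbers 1, 2 and 3, and the highest other of the 10 splits of the 6 libraries gave 0.18, so the hypothesis stays open. Of these genes 5 were called higher and 2 lower, and 48 and 9 with the replicate block.

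Adding a factor may act on the same genes in both settings. Of the genes called on adding Foxa.a to Bra, 100% had the same sign on adding it to Bra+Mnx. Of those called on adding Mnx to Bra+Foxa.a, 96.88% had the same sign on adding it to Bra. With the replicate block these shares were 92.6% of 672 genes and 90.0% of 309. The interaction test called 0 genes, with 162 at an unadjusted p under 0.05, 0 with edgeR and 1 with DESeq2, and with the replicate block 1 by limma and 6 by edgeR. The median standard error of the interaction over all genes was 0.289 (log2) without the block. So few calls therefore do not show that the settings are alike.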
